A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

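Total RNA from BY4741 yeast in Log phase liquid culture and from colonies on Day 2, Day 3 and Day 4, with 2 libraries per group and 8 in all, had been made into PAT-seq libraries and sequenced in 75-base reads on a SOLiD instrument by the authors. The deposited count table holds read counts per gene. Further deposited tables hold, per gene and library, counts of reads with a poly(A) tail and the mean poly(A) tail length of those reads in nt, with tail length values from 4 to 49 nt. A deposited gene table holds coordinates and, over all libraries together, read counts, mean tail length and the fraction of reads with a tail. From 42.8% (Log phase replicate 1) to 38.3% (Day 4 replicate 2) of the reads of genes assigned alike by both tables were tailed, a share that was lowest on Day 4. The aligner, the rule that decides whether a read has a tail and the genome build are not given in the sources used here. Coordinates are those of the gene table, and 5801 of its 5813 entries shared with the R64 annotation (99.8%) lay at identical positions. Poly(A) site use was not analysed here because the tables used are per gene, so the planned tests of site use and of its overlap with expression were not run.

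The count table has 6532 entries (149 of them merged overlapping genes), the tail length table lists 6936, and 6507 occur in both. Symbols came from the files for 5040 entries and from RefSeq for 242, and 1250 carry a systematic name alone. Of the 5850 entries above 100 reads, 449 had less than 0.5 times and 19 more than 2 times as many counts as reads in the gene table, and 4693 were within 10%. The 751 entries that were merged or differed beyond 2-fold are marked "assignment uncertain" or "uncertain" beside their values. Near-identical genes (HXT6 and HXT7, PHO11 and PHO12, ribosomal protein paralogs) share reads, so their single values are uncertain too.

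Expression was tested with edgeR 4.0.16 (TMM normalisation, filterByExpr, quasi-likelihood F test, 1 mean per group over all 8 libraries), and tail length with limma 3.58.1 (genes with at least 10 tailed reads in every library, weights equal to the tailed reads up to 100, empirical Bayes with a trend). Adjusted p is Benjamini-Hochberg over all genes tested, SE is the absolute log2 fold change over the square root of F for edgeR and the moderated SE for limma, and calls are at adjusted p under 0.05. Gene lists were written before the data were examined and tested with camera at a preset correlation of 0.01 and again with the correlation estimated per list. A list of Ty retrotransposons matched 0 entries and was not used. Principal components used log2 CPM with a prior count of 2. Spearman and Pearson correlations across genes used 10000 permutations of genes. Other software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

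The 5 comparisons were Day 2, Day 3 and Day 4 each against Log phase, Day 3 against Day 2 and Day 4 against Day 3. Named genes followed a rule: the 6 rising and 6 falling genes with the largest log2 fold change among those called with at least 50 CPM in the higher group. It adds up to 4 called members with the smallest p per list described and the 4 genes with the largest tail change in each direction. It also adds strain markers, genes followed between comparisons, and poly(A) factors whatever their p. Not every gene the rule names is printed, and 1 of the lists tested is not reported here. Members moving against their list, the genes of opposite calls and single small nucleolar RNAs (snoRNAs) were named after their values were seen.

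Tailed reads were 2765040 to 3782771 per library, and the 10 highest genes took 8.43% to 10.6% of counts. All columns were mapped to samples. The smallest count treated as detected, 3, covers counting error only, and so do intervals from counts. TMM factors were 0.825 and 0.794 for Log phase against 1.03 to 1.10 for colonies, so that scaling to total counts alone moved the median log2 fold change against Log phase by 0.38, 0.40 and 0.44 on Day 2, Day 3 and Day 4. The biological coefficient of variation was 0.128. Nothing in the labels says that the replicates are separate cultures, so p-values measure only the spread between these samples. Replicate numbers did not pair the libraries (r of deviations −0.0349 to 0.00554), and no block was used in the tests reported.

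Both tests were tried on simulated data, with changes added to 100 genes in each of 2 sizes on the Day 2 against Log phase design. edgeR on 5877 genes recovered 78% of 2-fold and 97% of 4-fold changes, with 6.42% of calls false, and limma on 5388 genes recovered 30% of changes of 2 nt and 76% of 4 nt, with 7.83% false. Alternatives covered normalisation, filters, tests, weights, a replicate block, tailed reads in place of all reads, and leaving out each library. Where a group is left with 1 library, it is assumed to vary like the other groups. rRNA, tRNA and snoRNA reads were summed from the tail tables and not tested per group.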

Results

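Poly(A) tails and transcript levels were measured by PAT-seq, which sequences the 3′ ends of polyadenylated RNA with part of the tail, in wild-type BY4741 yeast (a MATa laboratory strain auxotrophic for histidine, leucine, methionine and uracil). Log phase cells came from liquid culture, and colonies grown from such cells on solid medium were harvested on Day 2, Day 3 and Day 4, with 2 libraries per group. The question the labels name is whether gene expression and alternative polyadenylation are linked. Poly(A) site choice is not analysed here, and tail length is set beside expression instead. Changes in expression are given as log2 fold change ± SE with n = 2 libraries per group, group levels as TMM-normalised CPM ± SD, and tail changes in nt ± SE. A gene rose or fell, or is counted as higher or lower, where its adjusted p was below 0.05. The largest changes named are among such genes, for expression with at least 50 CPM in the higher group. Total counts ran from 6203115 (Day 2 replicate 1) to 8441949 (Log phase replicate 1).

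The libraries ordered by time. On the first principal component, which held 76.5% of the variance, Log phase lay at −76.3 and −77.6, Day 2 at −10.1 and −19.9, Day 3 at 38.4 and 34.9, and Day 4 at 54.0 and 56.6. The median absolute log2 difference between replicates was 0.17 in Log phase, 0.26 on Day 2, 0.19 on Day 3 and 0.14 on Day 4. TDH3, a glyceraldehyde-3-phosphate dehydrogenase gene, had the most counts in both Log phase libraries (1.40% and 1.28%). The aldolase gene FBA1 led on Day 2 (2.52% and 1.68%), and the stress protein gene HSP12 led on Day 3 and Day 4, with shares from 1.54% to 1.81%. Of the strain's auxotrophic markers, MET17 (MET15) had 0 counts in all 8 libraries, where 3 counts would be 0.355 to 0.484 CPM. LEU2 had 0 to 10 counts and URA3 0 to 8 per library. HIS3 is merged with its neighbour DED1 in the count table (573 to 708 counts) and gives no check; that merged entry was lower on Day 4 than in Log phase (−0.39±0.16, 0.05 with scaling to total counts).

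On Day 2, mRNAs for making ribosomes fell and mRNAs for respiration, gluconeogenesis, reserve carbohydrates and stress protection rose relative to Log phase. Cytosolic ribosomal protein genes had 132 of 137 lower (132 adjusted over the list alone, median −1.40); members with the smallest p were RPL17A (−2.51±0.15), RPL19A (−2.11±0.14), RPL40A (−2.19±0.15) and RPP1B (−2.26±0.16), and near-identical paralogs in this family share reads. The glyceraldehyde-3-phosphate dehydrogenase gene TDH1 (chromosome X, 338271 to 339269) rose most among genes with at least 50 CPM in the higher group, from 139.6±12.1 to 3979±599.6 CPM (4.83±0.17, adjusted p = 1.9e-15). PCK1, which encodes the gluconeogenic phosphoenolpyruvate carboxykinase (chromosome XI, 631152 to 632801), rose from 39.9±3.98 to 710.4±55.2 CPM (4.16±0.16, adjusted p = 8.51e-15). HXT1, a low-affinity glucose transporter gene, fell most among them, from 119±16.0 to 6.21±2.82 CPM (−4.22±0.26, adjusted p = 7.74e-12).

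Ribosome biogenesis genes had 106 of 111 lower (106 adjusted over the list alone, median −1.30), including RRS1 (−2.18±0.18), DBP3 (−2.76±0.22), CBF5 (−1.91±0.15) and LSG1 (−2.05±0.17). RNA polymerase I and III subunit genes had 18 of 19 lower (19 adjusted over the list alone, median −1.05), with RPA12 (−2.10±0.20), RPA135 (−1.83±0.18) and RPC31 (−1.64±0.18). Translation factor genes had 1 of 27 higher and 24 lower (1 and 24 adjusted over the list alone, median −1.05), led by YEF3 (−2.14±0.16), TIF3 (−2.05±0.16), TEF4 (−1.82±0.15) and EFT1 (−1.74±0.14); the exception that rose was CAM1 (0.69±0.14). Gluconeogenesis and glyoxylate genes had 19 of 21 higher and 1 lower (19 and 1 adjusted over the list alone, median 1.88), with CAT2 (3.41±0.17), YAT2 (3.06±0.17) and IDP2 (2.94±0.18), and ALD6 (−1.57±0.16), a cytosolic aldehyde dehydrogenase gene, fell. Glycolytic genes split, with 10 of 21 higher and 6 lower (10 and 6 adjusted over the list alone, median 0.06): ENO1 (2.36±0.14) and HXK1 (3.58±0.17, assignment uncertain) rose with TDH1 while PDC1 (−1.31±0.15) and PFK1 (−1.12±0.15) fell. TCA cycle genes had 15 of 16 higher (15 adjusted over the list alone, median 1.28), led by CIT3 (3.01±0.19), LSC2 (2.05±0.15) and CIT1 (1.92±0.15). Genes of the respiratory chain and ATP synthase had 34 of 38 higher (34 adjusted over the list alone, median 1.31), with COX5B (2.78±0.17), COX26 (2.68±0.16), NDE2 (2.79±0.18) and CYC7 (3.20±0.21). Nuclear genes for mitochondrial ribosomal proteins had 44 of 72 higher (46 adjusted over the list alone, median 0.52). Peroxisomal fatty acid oxidation genes had 13 of 18 higher and 1 lower (13 and 1 adjusted over the list alone, median 0.99), where the adenine nucleotide carrier gene ANT1 (−0.95±0.20) went against the rest.

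Environmental stress response genes had 54 of 56 higher (54 adjusted over the list alone, median 2.06), with the small heat-shock protein genes HSP26 (3.85±0.18) and HSP12 (3.51±0.16) and the cell wall gene SPI1 (3.55±0.17) among the smallest p. Trehalose and glycogen genes had 17 of 20 higher and 1 lower (17 and 1 adjusted over the list alone, median 1.79), led by the branching enzyme gene GLC3 (3.74±0.16) and PGM2 (2.99±0.15) and GSY1 (3.48±0.18); PGM1 (−0.89±0.26) fell. Stationary phase markers had 32 of 37 higher (32 adjusted over the list alone, median 2.00), with NQM1 (3.58±0.17). Autophagy genes had 31 of 44 higher and 1 lower (32 and 1 adjusted over the list alone, median 0.94, lower: ATG27 −0.60±0.15), with the vacuolar protease gene PRB1 (1.76±0.14) and AMS1 (2.01±0.16). Hexose transporters, a list that includes the glycerol symporter gene STL1, had 6 of 16 higher and 4 lower (6 and 4 adjusted over the list alone, median 0.88): HXT4 (4.53±0.25), HXT5 (2.92±0.16), HXT6 (4.65±0.27) and HXT7 (3.87±0.16) rose, where HXT6 and HXT7 are nearly identical and share reads. Other large rises were TFS1 (4.61±0.26), a carboxypeptidase Y inhibitor gene, and EGO4 (4.26±0.23), and other large drops FPR4 (−2.87±0.17), YDR222W (−2.77±0.30), PHO12 (−2.71±0.21) and TOS6 (−2.52±0.26, assignment uncertain), where PHO12 is nearly identical to PHO11. Replication and G1/S genes had 2 of 43 higher and 27 lower (2 and 27 adjusted over the list alone, median −0.65, higher: RNR2 0.41±0.14, RNR4 0.61±0.15), led by the ribonucleotide reductase gene RNR1 (−1.64±0.18). Genes of mitosis had 0 of 30 higher and 18 lower (1 and 20 adjusted over the list alone, median −0.63), led by the septum chitin synthase gene CHS2 (−1.61±0.16). Histone genes had 5 of 10 lower (5 adjusted over the list alone, median −0.37, 0.01 with scaling to total counts).

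Between Day 2 and Log phase, 3348 of 5930 genes tested changed, 1676 higher and 1672 lower, and 904 and 734 of these changed by more than 2-fold, by edgeR with n = 2 libraries per group; the largest adjusted p among the genes named as changed was 0.0187 (SYC1). Camera with the preset correlation gave adjusted p = 3.78e-32 (adjusted p = 0.191 with an estimated correlation) for ribosomal proteins and 3.48e-20 (adjusted p = 0.273 with an estimated correlation) for ribosome biogenesis. It gave adjusted p = 3.15e-10 (adjusted p = 0.191 with an estimated correlation) for respiration and 1.27e-20 (adjusted p = 0.198 with an estimated correlation) for the stress response. Medium, growth form and time differ together between colonies and Log phase, so no change can be assigned to 1 of them. Replicates differed most on Day 2.

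**Figure D1:**
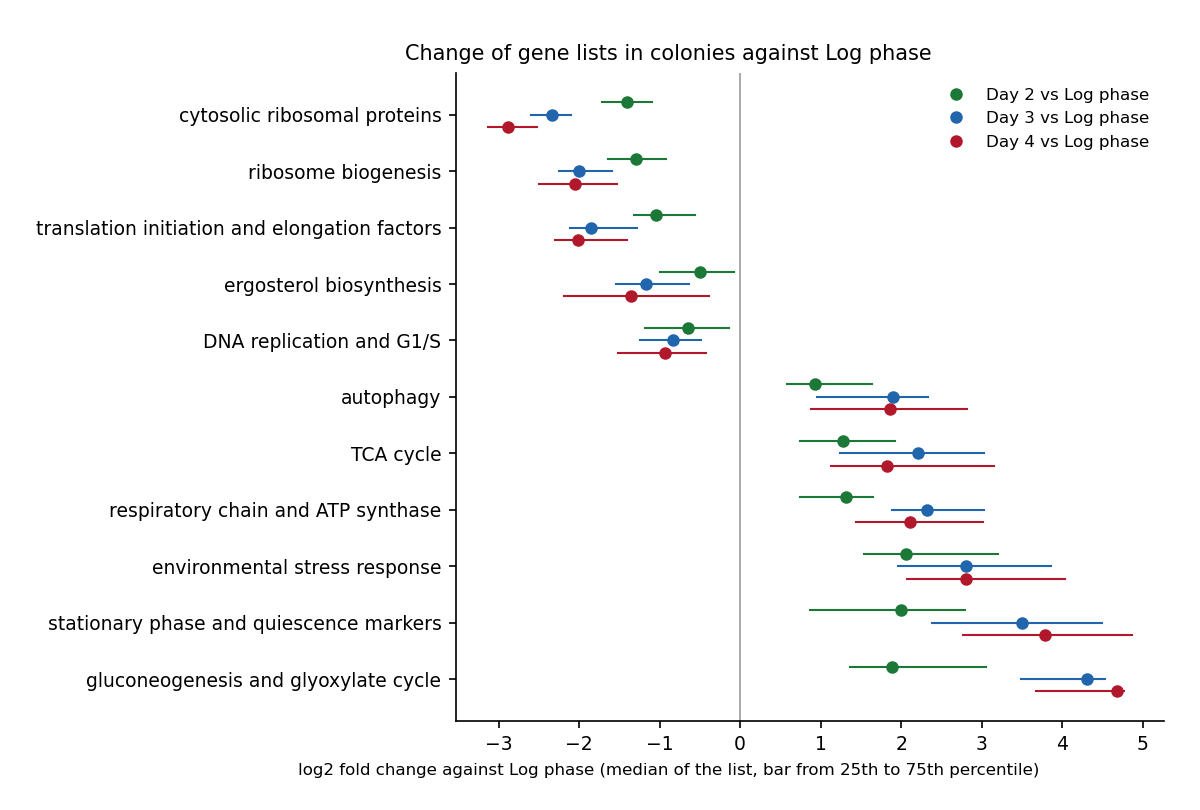
Median log2 fold change (points) with the 25th to 75th percentile (bars) of 11 gene lists on Day 2, Day 3 and Day 4 against Log phase. Ribosomal protein genes went from a median of −1.40 to −2.88 and gluconeogenesis genes from 1.88 to 4.68; no median drawn changed sign with another scaling.

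On Day 3, respiratory and gluconeogenic mRNAs stood far above Log phase and most glycolytic mRNAs below it. COX26, which encodes a subunit associated with cytochrome c oxidase (chromosome IV, 691014 to 691214), rose from 81.5±5.22 to 5846±558 CPM (6.16±0.19, adjusted p = 5.78e-17). The enolase gene ENO2 fell from 10980.5±128 to 1486±21.9 CPM (−2.89±0.14, adjusted p = 1.65e-14) and the pyruvate decarboxylase gene PDC1 from 8581±463 to 1145±188 CPM (−2.91±0.15, adjusted p = 8.89e-14). HSP12 (chromosome VI, 107256 to 107585) reached 15691±1754 CPM from 491±29.1 (5.00±0.17, adjusted p = 2.68e-16).

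Respiratory chain and ATP synthase genes had 37 of 38 higher (37 adjusted over the list alone, median 2.32), with COX7 (4.09±0.16), NDE2 (4.28±0.18) and QCR9 (4.26±0.20). Gluconeogenesis and glyoxylate genes had 20 of 21 higher and 1 lower (20 and 1 adjusted over the list alone, median 4.31), led by PCK1 (5.87±0.17), YAT2 (4.47±0.17), ICL1 (4.31±0.17) and CAT2 (4.33±0.17), where ICL1 encodes isocitrate lyase; ALD6 (−1.42±0.16) fell again. TCA cycle genes had 14 of 16 higher and 1 lower (14 and 1 adjusted over the list alone, median 2.21), with CIT3 (4.30±0.19), SDH4 (3.05±0.15) and KGD1 (3.03±0.16), and LSC1 (−0.54±0.16) on the other side. Fatty acid oxidation genes had 16 of 18 higher and 1 lower (16 and 1 adjusted over the list alone, median 2.09, lower: ANT1 −0.59±0.19), including the thiolase gene POT1 (3.92±0.20) and the acyl-CoA oxidase gene POX1 (3.50±0.20). Glycolytic genes had 6 of 21 higher and 15 lower (6 and 15 adjusted over the list alone, median −0.83); the 6 that rose were TDH1 (4.71±0.17), HXK1 (3.47±0.17, assignment uncertain), PDC6 (2.97±0.20), GLK1 (2.49±0.15, assignment uncertain), ENO1 (2.21±0.14) and PYK2 (0.87±0.25, assignment uncertain). Hexose transporters had 10 of 16 higher and 3 lower (10 and 3 adjusted over the list alone, median 1.88), with HXT5 (5.08±0.17) and HXT6 (5.77±0.29) higher and HXT1 (−5.58±0.29), HXT2 (−4.07±0.26) and HXT3 (−4.04±0.19) lower. Ammonium and acetate transporter genes had 5 of 6 higher and 1 lower (5 and 1 adjusted over the list alone, median 2.69), with ATO2 (4.93±0.19), ADY2 (4.72±0.19) and MEP2 (3.38±0.18) higher and ATO3 (−0.78±0.19) lower.

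Ribosomal protein genes had 135 of 137 lower (136 adjusted over the list alone, median −2.34), led by RPL9A (−3.42±0.16), RPS0B (−2.96±0.15), RPL22A (−2.89±0.14) and RPS16B (−3.02±0.15); RPS28B and RPL15B were not called. Ribosome biogenesis genes had 110 of 111 lower (110 adjusted over the list alone, median −2.01), with ERB1 (−3.26±0.17), CBF5 (−3.14±0.16), NOP1 (−3.13±0.17) and NOP58 (−3.01±0.18, assignment uncertain). RNA polymerase I and III subunits had 19 of 19 lower (19 adjusted over the list alone, median −1.57), with RPA43 (−2.95±0.17). Translation factors had 26 of 27 lower (26 adjusted over the list alone, median −1.86), with YEF3 (−3.55±0.17) and TEF4 (−2.84±0.15). Amino acid biosynthesis genes had 10 of 66 higher and 45 lower (11 and 46 adjusted over the list alone, median −1.15): HIS1 (−3.50±0.17), THR1 (−2.64±0.16) and ASN2 (−2.35±0.15) fell, and the NADP-glutamate dehydrogenase gene GDH3 (5.69±0.22) rose. Ergosterol genes had 1 of 24 higher and 19 lower (1 and 19 adjusted over the list alone, median −1.17), led by ERG6 (−2.91±0.16), NCP1 (−2.38±0.17) and ERG13 (−2.18±0.16), with ERG28 (0.74±0.17) as the member that rose. Stress response genes had 56 of 56 higher (56 adjusted over the list alone, median 2.81), with SPI1 (5.32±0.18), DDR2 (4.27±0.16, assignment uncertain) and HSP26 (5.03±0.19). Stationary phase markers had 35 of 37 higher (36 adjusted over the list alone, median 3.51), with RGI2 (6.29±0.22) and NQM1 (4.93±0.18). Trehalose and glycogen genes had 17 of 20 higher and 2 lower (17 and 2 adjusted over the list alone, median 2.49, lower: TPS3 −0.80±0.15, PGM1 −2.37±0.28), with GLC3 (4.36±0.17), PIG2 (4.73±0.21) and GAC1 (5.06±0.25). Autophagy genes had 39 of 44 higher and 1 lower (39 and 1 adjusted over the list alone, median 1.90, lower: ATG18 −1.05±0.19), with the receptor gene ATG39 (4.95±0.24) and ATG8 (4.24±0.24, assignment uncertain). The largest other rises were YPT53 (6.51±0.32, assignment uncertain) and SHH3 (5.80±0.28), an endosomal Rab gene and a homolog of SDH3, and the largest other drops PHO12 (−4.14±0.23), INA1 (−3.73±0.23) and CYS3 (−3.68±0.18), where CYS3 encodes cystathionine gamma-lyase.

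Replication and G1/S genes had 33 of 43 lower (33 adjusted over the list alone, median −0.84), led by the G1 cyclin gene CLN2 (−2.09±0.17) and the sliding clamp gene POL30 (−1.91±0.16). Mitosis genes had 17 of 30 lower (17 adjusted over the list alone, median −0.78) and histone genes 8 of 10 lower (8 adjusted over the list alone, median −0.75), with HHF2 (−1.80±0.14) and HTB2 (−1.82±0.16). In all, 4085 of 5930 genes tested changed, 2047 higher and 2038 lower (edgeR, n = 2), and the fitted change was more than 2-fold for 1376 and 1242 of these. The largest adjusted p among the genes named as changed was 0.0471 (ASG7). Camera gave adjusted p = 3.78e-32 (adjusted p = 0.191 with an estimated correlation) for ribosomal proteins and 4.07e-13 (adjusted p = 0.191 with an estimated correlation) for respiration. It gave 4.05e-09 (adjusted p = 0.198 with an estimated correlation) for gluconeogenesis and 1.4e-13 (adjusted p = 0.198 with an estimated correlation) for stationary phase markers.

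**Figure D2:**
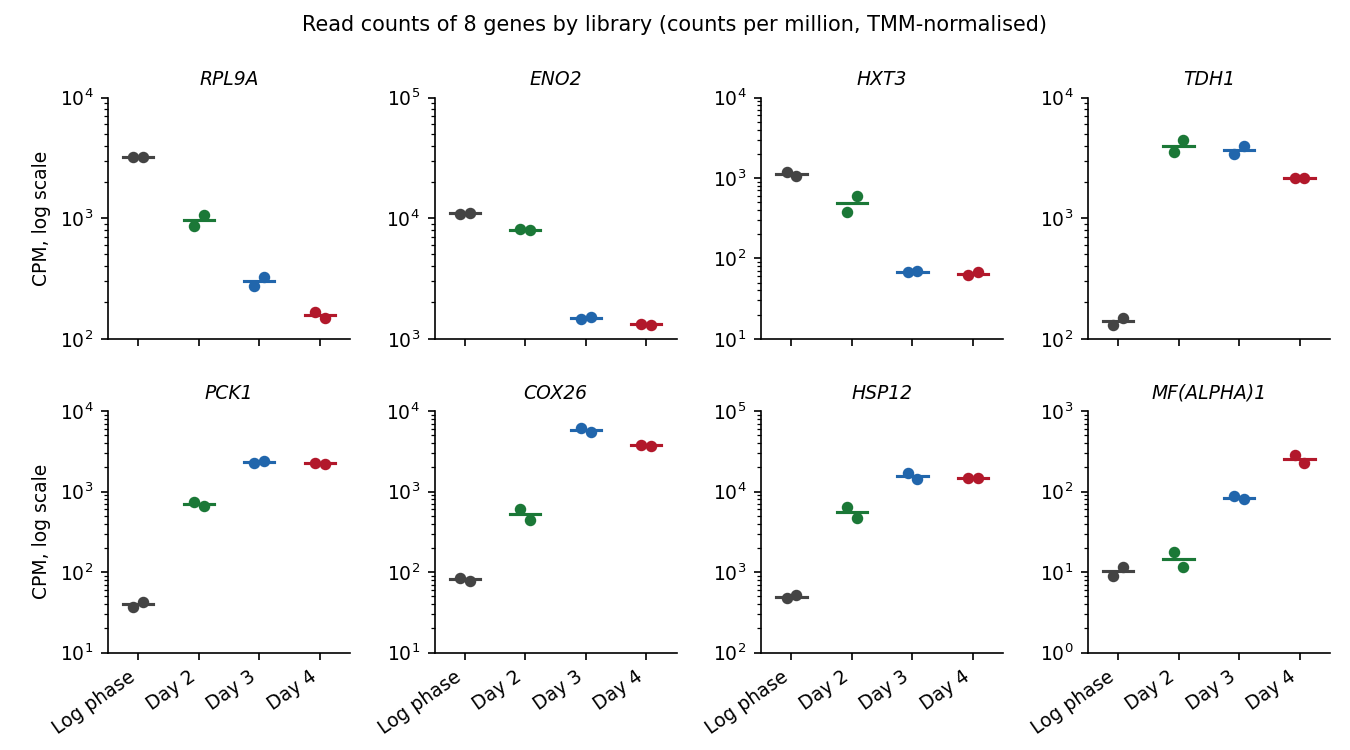
CPM (log axis) of 8 genes in each library (points), with the mean of the 2 libraries of a group (lines). Between Log phase and Day 4, RPL9A went from 3212±28.0 to 159±12.4 CPM and PCK1 from 39.9±3.98 to 2245±33.1 CPM (SD, n = 2).

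On Day 4, most gluconeogenesis and glyoxylate genes and stationary phase markers were higher than in Log phase. The carnitine acetyltransferase gene YAT1 rose from 101±3.16 to 2747±96.9 CPM (4.77±0.16, adjusted p = 1.32e-16), and SIP18, a hydrophilin gene, rose from 81.8±14.8 to 4195±30.7 CPM (5.68±0.20, adjusted p = 1.86e-16). RPL9A, a large-subunit ribosomal protein gene with a close paralog, fell from 3212±28.0 to 159±12.4 CPM (−4.34±0.17, adjusted p = 5.09e-16), and CYS3 fell from 1099±69.7 to 47.5±10.8 CPM (−4.53±0.19, adjusted p = 1.47e-15). MF(ALPHA)1, the alpha-factor pheromone gene (chromosome XVI, 193648 to 194145), rose in this MATa strain, from 10.2±1.87 to 256±36.5 CPM (4.65±0.22, adjusted p = 7.72e-15).

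Gluconeogenesis and glyoxylate genes had 20 of 21 higher and 1 lower (20 and 1 adjusted over the list alone, median 4.68), with PCK1 (5.82±0.17), ICL1 (4.74±0.17) and CAT2 (4.71±0.17) higher and ALD6 (−1.54±0.16) lower. TCA cycle genes had 14 of 16 higher and 1 lower (14 and 1 adjusted over the list alone, median 1.82), with CIT3 (4.46±0.19), SDH1 (4.02±0.18) and KGD1 (3.66±0.16) higher and LSC1 (−0.55±0.16) lower. Respiratory genes had 37 of 38 higher (37 adjusted over the list alone, median 2.11), with COX26 (5.53±0.18), NDE2 (4.80±0.18) and COX7 (4.18±0.16). Mitochondrial ribosomal protein genes split, with 13 of 72 higher and 29 lower (12 and 29 adjusted over the list alone, median −0.22, 0.22 with scaling to total counts): MNP1 (−1.50±0.16) and RSM26 (−1.38±0.15) fell and MRP8 (1.17±0.16) rose. Glycolytic genes had 6 of 21 higher and 15 lower (6 and 15 adjusted over the list alone, median −1.28), with TDH1 (3.94±0.16) and PDC6 (4.69±0.20) higher and ENO2 (−3.06±0.14) and HXK2 (−2.96±0.18) lower. Hexose transporters had 9 of 16 higher and 3 lower (9 and 3 adjusted over the list alone, median 2.03), with HXT5 (5.54±0.18) higher and HXT1 (−5.85±0.30), HXT2 (−4.83±0.28) and HXT3 (−4.12±0.19) lower. Ammonium and acetate transporters had 5 of 6 higher (5 adjusted over the list alone, median 3.01), led by ATO2 (5.59±0.19). Fatty acid oxidation genes had 16 of 18 higher and 1 lower (17 and 1 adjusted over the list alone, median 2.42, lower: ANT1 −0.63±0.19), led by POT1 (4.14±0.20).

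Ribosomal protein genes had 135 of 137 lower (136 adjusted over the list alone, median −2.88), with RPL22A (−3.70±0.15) and RPS19B (−3.87±0.16). Ribosome biogenesis genes had 110 of 111 lower (110 adjusted over the list alone, median −2.05), with CBF5 (−3.60±0.17) and NOP1 (−3.58±0.17). RNA polymerase I and III subunits had 19 of 19 lower (19 adjusted over the list alone, median −1.86), with RPA43 (−3.56±0.18). Translation factors had 25 of 27 lower (25 adjusted over the list alone, median −2.01), with YEF3 (−3.97±0.18) and TEF1 (−2.30±0.14). Histone genes had 10 of 10 lower (10 adjusted over the list alone, median −1.34), led by HHF2 (−3.19±0.15) and HTA2 (−2.94±0.15). Replication and G1/S genes had 2 of 43 higher and 32 lower (2 and 33 adjusted over the list alone, median −0.93), where RNR1 (−2.50±0.18) and CLN2 (−2.34±0.18) fell and RAD53 (1.00±0.30) and CTF4 (0.39±0.16, −0.03 with tailed reads) rose. Mitosis genes had 2 of 30 higher and 21 lower (2 and 21 adjusted over the list alone, median −1.26, higher: ASE1 0.73±0.27 uncertain, CDC15 0.80±0.22), led by CHS2 (−2.26±0.16) and CLB1 (−2.32±0.17). Stress response genes had 53 of 56 higher (53 adjusted over the list alone, median 2.80), with DDR2 (5.08±0.16, assignment uncertain) and SPI1 (5.42±0.18). Stationary phase markers had 36 of 37 higher (36 adjusted over the list alone, median 3.79). Trehalose and glycogen genes had 17 of 20 higher and 3 lower (17 and 3 adjusted over the list alone, median 2.53, lower: TPS3 −0.39±0.15, 0.05 with scaling to total counts, UGP1 −0.59±0.15, PGM1 −3.15±0.30), with GLC3 (4.70±0.17), PIG2 (5.17±0.22) and GAC1 (5.83±0.25). Autophagy genes had 38 of 44 higher and 2 lower (38 and 2 adjusted over the list alone, median 1.87, lower: ATG18 −0.53±0.19, ATG27 −0.71±0.15), with ATG39 (5.60±0.24) and AMS1 (3.70±0.17). Amino acid biosynthesis genes had 14 of 66 higher and 46 lower (14 and 46 adjusted over the list alone, median −1.39), with GDH3 (5.99±0.22) higher and HIS1 (−3.68±0.17) lower. Ergosterol genes had 19 of 24 lower (19 adjusted over the list alone, median −1.35), led by ERG6 (−3.17±0.16) and ERG4 (−3.24±0.21). The largest other rises were YPT53 (6.65±0.32, assignment uncertain), YMR206W (6.23±0.24), SHH3 (6.06±0.28) and YKL107W (5.95±0.35), and the largest other drops MIG2 (−4.59±0.23) and INA1 (−4.42±0.24), where MIG2 encodes a glucose repressor. In all, 4401 of 5930 genes tested changed, 2206 higher and 2195 lower (edgeR, n = 2), and the fitted change was more than 2-fold for 1622 and 1421 of these.

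For Day 4, camera gave adjusted p = 1.16e-31 (adjusted p = 0.191 with an estimated correlation) for ribosomal proteins and 5.53e-11 (adjusted p = 0.191 with an estimated correlation) for respiration. Gluconeogenesis had 3.2e-08 (adjusted p = 0.198 with an estimated correlation) and histones 0.00091 (adjusted p = 0.191 with an estimated correlation). The largest adjusted p among the genes named as changed was 0.0362 (DED1/HIS3).

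Between Day 2 and Day 3 in colonies, most respiratory and gluconeogenesis genes rose, and most ribosomal protein and glycolytic genes fell. ADH2, which encodes the alcohol dehydrogenase that oxidises ethanol, rose from 46.6±13.2 to 521±33.6 CPM (3.49±0.18, adjusted p = 3.75e-12), and ICL1 rose from 81.3±3.28 to 623±66.1 CPM (2.94±0.15, adjusted p = 3.75e-12). ENO2 fell from 7996±127 to 1486±21.9 CPM (−2.43±0.13, adjusted p = 9.15e-12), and the glucose transporter gene HXT4, which had been high on Day 2, fell from 622±17.0 to 70.4±18.2 CPM (−3.14±0.23, adjusted p = 4.64e-10).

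Gluconeogenesis and glyoxylate genes had 20 of 21 higher (20 adjusted over the list alone, median 1.74), with YAT1 (2.17±0.14) and ACS1 (2.44±0.18). Respiratory genes had 34 of 38 higher and 1 lower (34 and 1 adjusted over the list alone, median 1.20), with COX26 (3.48±0.17), COX7 (2.46±0.15), QCR8 (2.05±0.15) and COX13 (1.95±0.15); the hypoxic subunit gene COX5B (−0.61±0.16) fell. TCA cycle genes had 10 of 16 higher and 2 lower (10 and 2 adjusted over the list alone, median 0.57, lower: IDH2 −0.36±0.14, LSC1 −0.45±0.16), led by SDH1 (1.88±0.16) and SDH3 (1.77±0.15). Fatty acid oxidation genes had 14 of 18 higher (14 adjusted over the list alone, median 1.15), led by FOX2 (1.59±0.15). Ammonium and acetate transporters had 6 of 6 higher (6 adjusted over the list alone, median 1.47), led by ADY2 (2.72±0.17) and MEP2 (1.84±0.16). Stationary phase markers had 34 of 37 higher (34 adjusted over the list alone, median 1.49), with SIP18 (2.74±0.17), RGI2 (2.43±0.17) and GRE1 (2.40±0.17). Stress response genes had 34 of 56 higher and 6 lower (34 and 6 adjusted over the list alone, median 0.50): OM14 (1.67±0.14) and PHM7 (2.01±0.16) rose, and DDR48 (−1.23±0.15, assignment uncertain) and TFS1 (−0.57±0.22, 0.05 without Day 2 replicate 1) were among those that fell. Trehalose and glycogen genes had 13 of 20 higher and 4 lower (13 and 4 adjusted over the list alone, median 0.46, lower: TPS3 −0.81±0.15, GSY1 −0.71±0.16), with PIG2 (2.35±0.18) higher and UGP1 (−1.40±0.15) and PGM1 (−1.48±0.28) lower. Autophagy genes had 30 of 44 higher and 2 lower (31 and 2 adjusted over the list alone, median 0.67, lower: APE1 −0.79±0.15), with ATG39 (2.03±0.18) and ATG11 (1.46±0.15) higher and ATG18 (−0.99±0.19) lower. Other large rises were DPA10 (3.38±0.21), STL1 (2.93±0.19) and HSP30 (2.91±0.16), where HSP30 encodes a plasma membrane heat-shock protein.

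Ribosomal protein genes had 117 of 137 lower (119 adjusted over the list alone, median −0.88), with RPS9B (−2.47±0.15), RPL8A (−2.39±0.17), RPS11A (−2.04±0.16) and RPL8B (−1.98±0.15). Ribosome biogenesis genes had 4 of 111 higher and 69 lower (4 and 74 adjusted over the list alone, median −0.74), with HAS1 (−1.64±0.17) and GAR1 (−1.51±0.16) lower and UTP20 (0.50±0.17), RRP36 (0.59±0.22), DBP3 (0.72±0.21) and RRS1 (0.79±0.17) higher. Translation factors had 1 of 27 higher and 21 lower (1 and 21 adjusted over the list alone, median −0.82), with HYP2 (−1.62±0.14) and FUN12 (−1.76±0.15) lower and SUI1 (0.72±0.14) higher. RNA polymerase I and III subunits had 2 of 19 higher and 10 lower (2 and 11 adjusted over the list alone, median −0.57, higher: RPA12 0.52±0.19, RPC11 0.40±0.16). Glycolytic genes had 1 of 21 higher and 16 lower (1 and 16 adjusted over the list alone, median −0.88), with TDH2 (−1.56±0.14) and PDC1 (−1.60±0.15) lower and PDC6 (2.18±0.18) higher. Hexose transporters had 7 of 16 higher and 5 lower (7 and 5 adjusted over the list alone, median 1.02), with HXT3 (−2.83±0.18). Mitochondrial ribosomal protein genes had 5 of 72 higher and 27 lower (5 and 27 adjusted over the list alone, median −0.25). Ergosterol genes had 3 of 24 higher and 17 lower (4 and 17 adjusted over the list alone, median −0.65, higher: ERG1 0.75±0.18, ERG28 0.70±0.17, IDI1 0.40±0.16), led by ERG24 (−1.57±0.16) and ERG4 (−1.85±0.19). Amino acid biosynthesis genes had 5 of 66 higher and 32 lower (5 and 32 adjusted over the list alone, median −0.36), led by ASN2 (−1.84±0.15) and HIS1 (−1.81±0.16). Replication genes had 5 of 43 higher and 14 lower (5 and 14 adjusted over the list alone, median −0.34). Mitosis genes had 2 of 30 higher and 9 lower (2 and 8 adjusted over the list alone, median −0.13, higher: IQG1 0.47±0.17, CDC15 1.00±0.23). Histone genes had 1 of 10 higher and 7 lower (1 and 8 adjusted over the list alone, median −0.56), where HTA2 (−1.14±0.14) fell and the variant H2A.Z gene HTZ1 (0.73±0.14) rose. Another large drop was GCN1 (−2.41±0.18). In all, 2930 of 5930 genes tested changed, 1438 higher and 1492 lower, and 659 and 495 of these changed by more than 2-fold (edgeR, n = 2), and the largest adjusted p among the genes named as changed was 0.0437 (IDI1). Camera gave adjusted p = 3.08e-23 (adjusted p = 0.198 with an estimated correlation) for ribosomal proteins, 2.39e-10 (adjusted p = 0.191 with an estimated correlation) for gluconeogenesis and 4.07e-13 (adjusted p = 0.198 with an estimated correlation) for stationary phase markers.

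Between Day 3 and Day 4 fewer genes changed, and most cytosolic and mitochondrial ribosomal protein genes fell. AGA1, the anchor subunit gene of a-agglutinin, rose from 18.0±1.25 to 75.3±4.22 CPM (2.06±0.20, adjusted p = 6.27e-07), and PDC6, a minor pyruvate decarboxylase gene, from 66.7±7.38 to 219±15.3 CPM (1.72±0.16, adjusted p = 4.69e-07). The glucanosyltransferase gene GAS1 fell from 250.0±103 to 79.2±8.89 CPM (−1.66±0.20, adjusted p = 4.61e-06) and the ergosterol gene ERG4 from 143±47.9 to 47.4±7.63 CPM (−1.59±0.20, adjusted p = 9.35e-06).

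Ribosomal protein genes had 0 of 137 higher and 98 lower (1 and 106 adjusted over the list alone, median −0.54), with RPS13 (−0.97±0.14), RPL14A (−0.99±0.15) and RPL29 (−1.02±0.15). Mitochondrial ribosomal protein genes had 46 of 72 lower (52 adjusted over the list alone, median −0.56), with MNP1 (−1.35±0.16), MRPL50 (−1.09±0.16) and MRPL27 (−1.09±0.16). Ribosome biogenesis genes had 4 of 111 higher and 12 lower (1 and 3 adjusted over the list alone, median −0.12, higher: NOP2 0.62±0.21, UTP22 0.59±0.19, RRP14 0.50±0.18), where EMG1 (−0.93±0.16) fell and MDN1 (0.54±0.15) rose. Translation factors had 2 of 27 higher and 8 lower (3 and 10 adjusted over the list alone, median −0.21, higher: TIF4631 0.88±0.26 uncertain, −0.02 with tailed reads, NIP1 0.45±0.15 uncertain), with SUI3 (−0.71±0.14). RNA polymerase I and III subunits had 2 of 19 higher and 6 lower (2 and 6 adjusted over the list alone, median −0.07, higher: RPO31 0.50±0.16, RET1 0.51±0.16). Histone genes had 8 of 10 lower (8 adjusted over the list alone, median −0.74), led by HHF2 (−1.39±0.14) and HTA2 (−1.31±0.15). Mitosis genes had 2 of 30 higher and 6 lower (2 and 6 adjusted over the list alone, median −0.31, higher: BUB1 0.70±0.22, CDC15 0.61±0.22), led by CLB1 (−1.43±0.16). Replication genes had 1 of 43 higher and 7 lower (1 and 7 adjusted over the list alone, median −0.14, higher: POL2 0.60±0.20). Respiratory genes had 1 of 38 higher and 12 lower (1 and 13 adjusted over the list alone, median −0.23), with COX5B (−1.08±0.16) and ATP20 (−0.71±0.14) lower and NDE2 (0.53±0.14) higher. TCA cycle genes had 2 of 16 higher and 3 lower (2 and 5 adjusted over the list alone, median −0.11), where SDH1 (0.92±0.15) rose and SDH3 (−0.76±0.15) fell. Gluconeogenesis genes had 5 of 21 higher and 3 lower (6 and 3 adjusted over the list alone, median 0.15), with YAT1 (0.87±0.14) and SIP4 (1.05±0.22) higher and IDP2 (−0.65±0.16) lower. Glycolytic genes had 2 of 21 higher and 9 lower (2 and 10 adjusted over the list alone, median −0.32, higher: PDC1 0.48±0.14, PDC6 1.72±0.16), with HXK1 (−1.29±0.16, assignment uncertain) and HXK2 (−1.25±0.17). Fatty acid oxidation genes had 5 of 18 higher (5 adjusted over the list alone, median 0.25). Hexose transporters had 3 of 16 higher and 4 lower (3 and 4 adjusted over the list alone, median 0.13, mean −0.04), with HXT7 (−1.48±0.15) and HXT4 (−1.56±0.24) lower.

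Stress response genes divided, with 15 of 56 higher and 14 lower (15 and 17 adjusted over the list alone, median −0.01, mean 0.06, 0.03 with scaling to total counts, 0.02 with tailed reads): the catalase gene CTT1 (1.38±0.16) and the repressor gene XBP1 (1.61±0.18) rose. Stationary phase markers had 9 of 37 higher and 3 lower (9 and 3 adjusted over the list alone, median 0.06, lower: RGI2 −0.47±0.16), where the vitamin B6 synthesis gene SNZ1 (1.64±0.15) rose and RGI1 (−1.32±0.26) and STF2 (−1.06±0.20) fell. Trehalose and glycogen genes had 7 of 20 higher and 1 lower (10 and 3 adjusted over the list alone, median 0.31, lower: UGP1 −0.65±0.15), with TSL1 (0.79±0.15). Autophagy genes had 8 of 44 higher and 5 lower (9 and 5 adjusted over the list alone, median 0.13). Amino acid genes had 9 of 66 higher and 16 lower (10 and 21 adjusted over the list alone, median −0.21), with CPA1 (1.24±0.18) higher and GDH1 (−0.99±0.16) lower. Ergosterol genes had 1 of 24 higher and 8 lower (1 and 8 adjusted over the list alone, median −0.31), where ERG25 (1.12±0.16) rose. Ammonium and acetate transporters had 2 of 6 higher and 1 lower (3 and 1 adjusted over the list alone, median 0.32, lower: MEP3 −0.59±0.17). Other large rises were YDL218W (2.14±0.17) and HBT1 (2.01±0.21), and other large drops SUR7 (−1.49±0.17) and GND1 (−1.44±0.15), where SUR7 encodes an eisosome protein and GND1 6-phosphogluconate dehydrogenase. In all, 1570 of 5930 genes tested changed, 702 higher and 868 lower, and 154 and 89 of these changed by more than 2-fold (edgeR, n = 2), and the largest adjusted p among the genes named as changed was 0.0459 (FET4). Camera gave adjusted p = 2.05e-13 (adjusted p = 0.191 with an estimated correlation) for mitochondrial ribosomal proteins, 4.86e-20 (adjusted p = 0.218 with an estimated correlation) for ribosomal proteins and 3.14e-05 (adjusted p = 0.191 with an estimated correlation) for histones. The number called moved with single libraries: it was 998 and 883 without Day 3 replicate 1 or 2, and 786 and 608 without Day 4 replicate 1 or 2.

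Several alpha-cell genes were higher on Day 3 and Day 4 than in Log phase in this MATa strain. Of the 8 measured, 3 were higher on Day 2, 6 on Day 3 and 6 on Day 4 (2, 6 and 6 adjusted over the list alone). Of the 4 not marked uncertain (MF(ALPHA)1, MF(ALPHA)2, SAG1 and HMLALPHA2), 1, 3 and 3 were. MATALPHA and HML share sequence, and without HMLALPHA2 the calls left of these were MF(ALPHA)1 and SAG1 on Day 3 and Day 4. Camera gave adjusted p = 0.0317 (adjusted p = 0.266 with an estimated correlation) on Day 4. MF(ALPHA)1 was 10.2±1.87 CPM in Log phase, 14.7±4.58 on Day 2, 83.9±5.54 on Day 3 and 256±36.5 on Day 4. The alpha-agglutinin gene SAG1 rose late, from 20.5±0.315 to 72.4±0.509 CPM (1.82±0.19, adjusted p = 1.19e-08). STE3 (2.10±0.55, uncertain), BUD5/MATALPHA2 (0.96±0.18, uncertain) and HMLALPHA2 (1.22±0.26) rose by Day 3, where BUD5 is a merged neighbour and not an alpha-cell gene. MF(ALPHA)2 and MATALPHA1 were not called in any comparison, and from Day 3 to Day 4 only MF(ALPHA)1 and SAG1 were. HMRA1 shares its sequence with MATa1, which a MATa strain carries and the gene table does not list, so its reads cannot be placed at 1 locus. They rose from 102±11.2 to 599.8±80.3 CPM (2.55±0.16, adjusted p = 1.72e-12). The a-cell mating genes split on Day 3, with 4 of 17 higher and 9 lower (4 and 9 adjusted over the list alone, median −0.64, higher: AGA2 0.38±0.15, ASG7 0.49±0.22, FUS2 0.84±0.30): the alpha-factor protease gene BAR1 (−1.70±0.15) and the alpha-factor receptor gene STE2 (−0.91±0.15) fell.

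Poly(A) tails were longest on Day 2 and shorter on Day 3 and Day 4. The median over 5388 genes, averaged over the 2 libraries of a group, was 19.4±0.408 nt in Log phase, 20.4±0.100 nt on Day 2, 18.3±0.0107 nt on Day 3 and 18.0±0.161 nt on Day 4 (SD, n = 2). The steps from Log phase to Day 2 and from Day 2 to Day 3 exceeded the spread between libraries. CIT2, the peroxisomal citrate synthase gene, lengthened on Day 2 and shortened by Day 3: 4.69±0.382 nt, adjusted p = 5.29e-07, from 19.5±0.164 to 24.2±0.0760 nt, then −5.78±0.382 nt, adjusted p = 1.23e-08 to 18.4±0.0690 nt. TPS1, the trehalose phosphate synthase gene, went from 24.7±1.10 nt in Log phase to 19.0±0.460 nt on Day 3 (−5.72±0.699 nt, adjusted p = 7.52e-05). EIS1, an eisosome gene, lengthened by Day 4 against the general trend (9.61±0.876 nt, adjusted p = 1.28e-06).

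**Figure D3:**
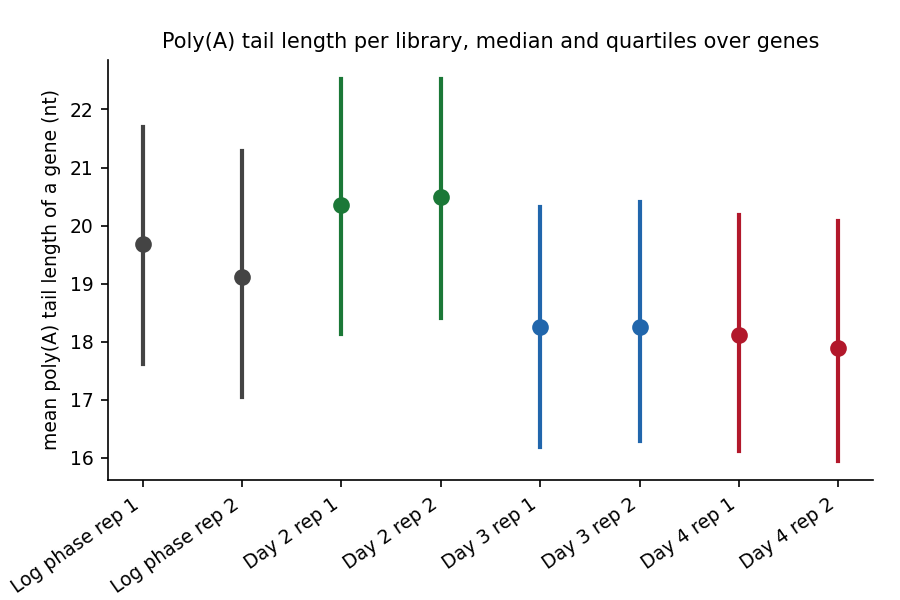
Mean poly(A) tail length per gene (nt) in each library, as the median over 5388 genes (points) with the 25th to 75th percentile (bars). Library medians ran from 17.9 nt (Day 4 replicate 2) to 20.5 nt (Day 2 replicate 2).

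On Day 2, 588 of 5388 genes changed tail length against Log phase (limma, n = 2), 549 longer and 39 shorter, with a median change over all genes of 0.963 nt. That number was 160 without Log phase replicate 2 and 238 without Day 2 replicate 1. The largest lengthening was in HMI1 (11.9±3.16 nt) and MSH1 (10.3±2.41 nt), which encode a mitochondrial DNA helicase and a mitochondrial mismatch repair protein, and the largest shortening in RNY1 (−8.01±2.07 nt), YMR114C (−7.08±1.40 nt) and MAE1 (−6.98±1.67 nt). Gluconeogenesis genes had 8 of 19 longer and 1 shorter (8 and 1 adjusted over the list alone, median 1.46 nt, shorter: CAT2 −2.69±0.842 nt), with JEN1 (4.29±0.481 nt) and ALD6 (4.13±0.617 nt), where JEN1 encodes the lactate transporter. Ribosomal protein genes had 34 of 135 longer and 5 shorter (45 and 9 adjusted over the list alone, median 0.790 nt), with RPL7B (5.52±0.582 nt) and RPP1B (3.68±0.565 nt). Genes of ribosome biogenesis had 20 of 111 longer (26 adjusted over the list alone, median 1.70 nt), with NHP2 (6.63±0.931 nt) and RRS1 (7.24±1.30 nt). Stress response genes had 9 of 55 longer and 3 shorter (14 and 5 adjusted over the list alone, median 0.647 nt, shorter: SOD1 −2.30±0.572 nt, TFS1 −5.42±1.15 nt): SPI1 (3.11±0.446 nt) lengthened and HSP12 (−1.99±0.374 nt) shortened. Stationary phase markers had 11 of 35 longer and 1 shorter (13 and 2 adjusted over the list alone, median 1.35 nt), led by SPG1 (4.33±0.422 nt). Amino acid genes had 8 of 65 longer and 1 shorter (11 and 1 adjusted over the list alone, median 0.938 nt, shorter: GDH3 −2.88±0.704 nt), led by the branched-chain synthesis gene ILV5 (5.65±0.635 nt). Glycolytic genes had 0 of 21 longer and 2 shorter (2 and 2 adjusted over the list alone, median −0.581 nt), PGI1 (−3.43±0.595 nt) and ADH1 (−2.32±0.454 nt). Iron genes had 4 of 25 longer (9 adjusted over the list alone, median 1.42 nt), led by the siderophore transporter gene SIT1 (4.82±0.509 nt). Cell wall genes had 11 of 33 longer and 1 shorter (11 and 1 adjusted over the list alone, median 1.09 nt, shorter: CHS1 −4.26±0.974 nt), led by CWP1 (3.64±0.521 nt). Respiratory genes had 10 of 36 longer and 0 shorter (16 and 2 adjusted over the list alone, median 1.25 nt), with QCR8 (3.01±0.476 nt) and COX26 (2.17±0.367 nt). Histone genes had 4 of 10 longer (6 adjusted over the list alone, median 1.43 nt) and mitochondrial ribosomal protein genes 10 of 72 longer and 0 shorter (11 and 1 adjusted over the list alone, median 1.39 nt).

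From Day 2 to Day 3, 1606 genes changed tail length (limma, n = 2), 1568 shorter and 38 longer, with a median over all genes of −1.95 nt. That number was 829 without Day 3 replicate 1 and 997 without Day 3 replicate 2. The largest shortening was in RPP1 (−12.5±2.32 nt), FAP7 (−11.2±1.76 nt) and PAP1 (−10.7±3.05 nt), where PAP1 encodes the poly(A) polymerase and RPP1 a subunit of RNase P, and the largest lengthening in MAE1 (4.58±1.67 nt) and NOP2 (4.17±1.26 nt). Trehalose and glycogen genes had 9 of 19 shorter (9 adjusted over the list alone, median −1.93 nt), with TPS1 (−5.99±0.699 nt) and TSL1 (−3.68±0.578 nt). Autophagy genes had 16 of 39 shorter (19 adjusted over the list alone, median −2.40 nt), with ATG22 (−6.77±1.07 nt). Genes of ribosome biogenesis had 3 of 111 longer and 28 shorter (3 and 28 adjusted over the list alone, median −1.84 nt, longer: NSR1 1.88±0.596 nt, YTM1 3.54±1.02 nt), with NOC2 (−10.6±1.45 nt) and RRS1 (−7.50±1.30 nt). Ribosomal protein genes split, with 11 of 135 longer and 23 shorter (10 and 23 adjusted over the list alone, median −0.316 nt), led by RPL7B (−5.80±0.582 nt) and RPS27A (−4.14±0.608 nt). Respiratory genes had 18 of 36 shorter (19 adjusted over the list alone, median −1.80 nt), with COX7 (−4.05±0.557 nt) and COX9 (−3.82±0.589 nt). Amino acid genes had 15 of 65 shorter (12 adjusted over the list alone, median −1.28 nt), with ILV5 (−4.50±0.635 nt). Stress response genes had 0 of 55 longer and 24 shorter (1 and 24 adjusted over the list alone, median −1.45 nt). The enolase gene ENO2 (1.64±0.378 nt) lengthened.

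Against Log phase, 493 genes changed tail length on Day 3 (73 longer, 420 shorter, median −0.972 nt) and 884 on Day 4 (140 longer, 744 shorter, median −1.16 nt; limma, n = 2). With each library's median subtracted the balance of the calls turned over, to 296 longer and 117 shorter on Day 3 and 480 longer and 239 shorter on Day 4. Of the calls without subtraction, 190 on Day 3 and 379 on Day 4 were kept, and 0 changed direction. The balance moved because most calls were lost, largely shorter ones, and other genes were called. Without 1 library, the number fell on Day 3 to 170 (Log phase replicate 1), 224 (Day 3 replicate 1) and 209 (Day 3 replicate 2). On Day 4 it fell to 390 (Log phase replicate 1), 587 (Day 4 replicate 1) and 458 (Day 4 replicate 2). Ribosomal protein genes divided on Day 4, with 19 of 135 longer and 15 shorter (20 and 18 adjusted over the list alone, median 0.203 nt, mean −0.0180 nt): RPL22A (4.26±0.486 nt) lengthened and RPL15A (−5.89±0.648 nt), RPS27A (−5.52±0.608 nt) and RPL24A (−4.44±0.504 nt) shortened. Glycolytic genes also divided, with 4 of 21 longer and 5 shorter (4 and 5 adjusted over the list alone, median −0.407 nt): PGK1 (2.51±0.390 nt) and ENO2 (2.24±0.378 nt) lengthened and ADH1 (−3.50±0.454 nt) shortened. Gluconeogenesis genes had 5 of 19 longer and 1 shorter (5 and 3 adjusted over the list alone, median 0.198 nt), with JEN1 (3.45±0.481 nt) and ALD6 (3.94±0.617 nt) longer and PCK1 (−2.62±0.445 nt) shorter. Respiratory genes had 2 of 36 longer and 8 shorter (2 and 11 adjusted over the list alone, median −0.605 nt, longer: COX8 3.91±0.441 nt uncertain, ATP7 2.39±0.512 nt), with COX9 (−5.33±0.589 nt) and ATP18 (−4.92±0.520 nt). Stress response genes had 8 of 55 longer and 16 shorter (9 and 18 adjusted over the list alone, median −0.611 nt), with TPS1 (−5.60±0.699 nt), TSL1 (−4.47±0.578 nt) and HSP12 (−2.31±0.374 nt). Amino acid genes had 3 of 65 longer and 4 shorter (3 and 4 adjusted over the list alone, median −0.426 nt), with GDH3 (−4.88±0.704 nt). The largest shortening on Day 4 was in LDB18 (−13.3±1.86 nt) and RNH70 (−13.2±2.86 nt), and on Day 3 in PUT7 (−10.2±2.94 nt), YMR114C (−9.83±1.40 nt) and RCY1 (−9.01±2.65 nt). Between Day 3 and Day 4 limma called 0 of 5388 genes, with 475 at an unadjusted p under 0.05 and a median change of −0.186 nt. The largest adjusted p among the tail changes named was 0.0444 (CAT2) on Day 2, 0.0369 (RCY1) on Day 3 and 0.00309 (RNH70) on Day 4 against Log phase, and 0.0452 (MAE1) from Day 2 to Day 3.

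Of 170 tail tests by camera with the preset correlation, 12 had adjusted p under 0.05, the smallest for ribosomal proteins from Day 2 to Day 3, 2.12e-09 (adjusted p = 0.77 with an estimated correlation), relative to the general shortening. The others were ribosomal proteins on Day 3, 2.8e-09 (adjusted p = 0.77 with an estimated correlation), and Day 4, 2.97e-05 (adjusted p = 0.784 with an estimated correlation), against Log phase. Ribosome biogenesis had 0.0217 (adjusted p = 0.77 with an estimated correlation) on Day 2 and 0.00493 (adjusted p = 0.77 with an estimated correlation) on Day 3. For glycolysis the values were 0.0085 (adjusted p = 0.77 with an estimated correlation) on Day 2 and, from Day 2 to Day 3, 0.0204 (adjusted p = 0.784 with an estimated correlation). Gluconeogenesis on Day 4 had 0.0202 (adjusted p = 0.77 with an estimated correlation) and methionine genes on Day 3 0.0391 (adjusted p = 0.77 with an estimated correlation). Translation factors completed the 12, with 0.0202 (adjusted p = 0.77 with an estimated correlation) on Day 3, 0.021 (adjusted p = 0.77 with an estimated correlation) on Day 4 and 0.0272 (adjusted p = 0.77 with an estimated correlation) from Day 2 to Day 3. With each library's median subtracted, 280 genes changed on Day 2 (141 longer, 139 shorter) and 487 from Day 2 to Day 3 (338 longer, 149 shorter). Which genes are called, and the balance of longer and shorter, thus depend partly on the change shared by the whole library.

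Expression changes and tail changes were weakly and negatively related across genes. Over 5218 genes, which are not independent replicates, Spearman's rho was −0.203 for Day 2, −0.252 for Day 3 and −0.217 for Day 4 against Log phase and −0.214 for Day 3 against Day 2 (permutation p = 1e-04 each, two-sided). That p is the smallest that 10000 permutations can give, and its Benjamini-Hochberg value over the 5 computed is 0.000125. Pearson's r was −0.199, −0.204, −0.178 and −0.171 (permutation p = 1e-04 each, Benjamini-Hochberg p = 0.000125). For Day 4 against Day 3, rho was 0.0101 (permutation p = 0.464, Benjamini-Hochberg p = 0.464) and r −0.00645 (permutation p = 0.639, Benjamini-Hochberg p = 0.639). Among single genes, PCK1 rose in level and its tails shortened on Day 4 (−2.62±0.445 nt), and GDH3 and HSP12 did the same, while the tails of JEN1, which also rose (3.97±0.17), lengthened.

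**Figure D4:**
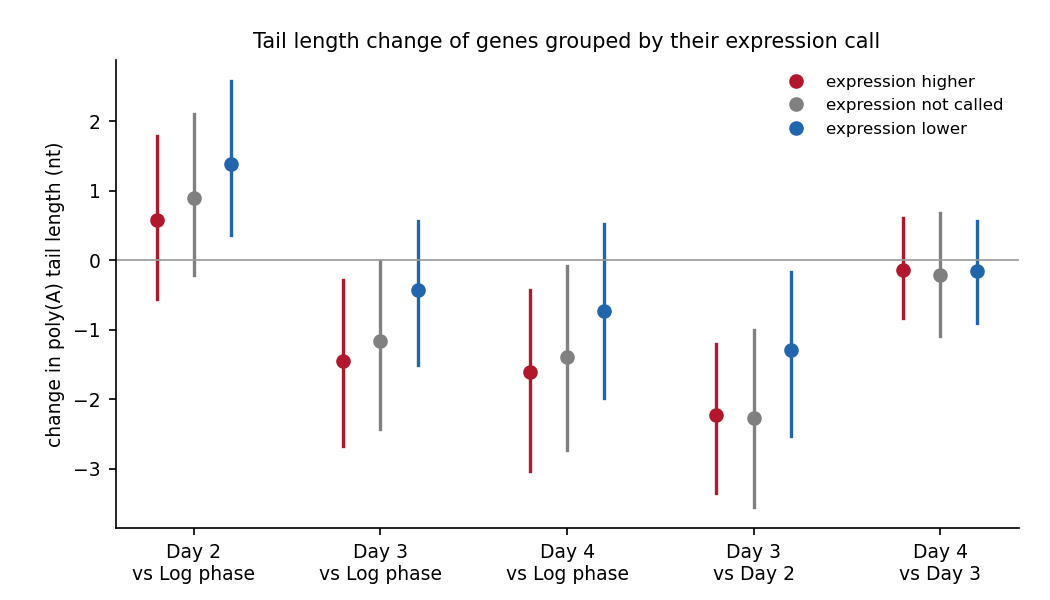
Median change in tail length in nt (points) with the 25th to 75th percentile (bars) of genes grouped by expression call, in the 5 comparisons. From Log phase to Day 2 the medians were 0.578 nt for the 1510 genes higher in expression, 0.896 nt for the 2098 not called and 1.38 nt for the 1610 lower.

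Genes for polyadenylation and deadenylation were more often lower than higher in colonies against Log phase, which depended on the scaling. On Day 2 they had 4 of 41 higher and 21 lower (4 and 21 adjusted over the list alone, median −0.48, higher: YTH1 0.84±0.25, GLC7 1.39±0.23 uncertain, SYC1 0.68±0.24, CDC36 0.43±0.15), on Day 3 6 of 41 higher and 23 lower (6 and 23 adjusted over the list alone, median −0.64) and on Day 4 6 of 41 higher and 21 lower (6 and 21 adjusted over the list alone, median −0.44, 0.0024 with scaling to total counts). Camera gave adjusted p = 0.00696 (adjusted p = 0.266 with an estimated correlation) on Day 2, 0.0161 (adjusted p = 0.289 with an estimated correlation) on Day 3 and 0.0765 (adjusted p = 0.388 with an estimated correlation) on Day 4. With scaling to total counts 9 were higher and 8 lower on Day 2, 9 and 13 on Day 3 and 11 and 9 on Day 4. PAB1, the poly(A)-binding protein gene, fell from 2505±347 to 821±84.7 CPM (−1.61±0.15, adjusted p = 2.51e-09) and rose from Day 3 to Day 4 (0.77±0.14, adjusted p = 0.000436). The deadenylase gene CCR4 (−1.38±0.21) fell on Day 2 and rose from Day 3 to Day 4 (1.16±0.21). NRD1 (−2.00±0.19) and NAB2 (−1.33±0.20) fell on Day 2, CAF40 (−1.39±0.18) and CDC39 (−1.19±0.15) were lower on Day 3 and NOT5 (−1.43±0.15) and SWD2 (−1.76±0.19) on Day 4. The cleavage factor genes RNA14 (0.95±0.16) and MPE1 (0.84±0.17) rose from Day 2 to Day 3, when the list had 5 of 41 higher and 5 lower (4 and 5 adjusted over the list alone, median −0.07). The mRNA-binding protein gene PUF3 (1.05±0.16) rose from Day 3 to Day 4, when the list had 8 of 41 higher and 4 lower (8 and 4 adjusted over the list alone, median 0.10, lower: SSU72 −0.64±0.19, HRP1 −0.48±0.16). PAP1 was not called in expression in any of the 5 comparisons. Their own tails had 5 of 40 longer (7 adjusted over the list alone, median 1.35 nt) on Day 2, with POP2 (4.52±1.18 nt) and PAB1 (1.86±0.461 nt). From Day 2 to Day 3 they had 13 of 40 shorter (14 adjusted over the list alone, median −2.35 nt), with NRD1 (−6.68±1.08 nt) and POP2 (−6.42±1.18 nt).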

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

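The tests of a uniform shift from Log phase to Day 2, of a lower mRNA yield and of reads assigned to different overlapping genes were chosen after the results they bear on were seen; the other 5 tests were written before. Tail lengths were longer on Day 2 and shorter on Day 3 and Day 4, and a uniform shift of all tails in a library would move the tails of rRNA and tRNA reads too. From Day 2 to Day 3 their pooled mean changed by −0.822 nt beside −2.167 nt for the median gene (the SDs of these 4 group means add up to 0.681 nt), a fall to which a changed mix of the classes adds. By class, rRNA tails changed by −0.286 nt (to 13.4±0.0295 nt), tRNA tails by −0.655 nt (1.51 nt from the median gene, where the SDs add up to 1.69 nt) and snoRNA tails by −2.36 nt (to 16.0±0.160 nt). The mean of the 3 classes changed by −1.10 nt, 1.067 nt from the median gene, where the SDs add up to 1.049 nt. The pooled mean lay beyond the spread. By single class only rRNA did, 1.88 nt from the median gene, where the SDs add up to 0.497 nt. Whether rRNA reads hold added tails or arise by internal priming on A-rich stretches was not tested. A shift of all RNAs by the same length is therefore not excluded at this step. A shift in proportion to length, which was not tested, could also contribute. From Log phase to Day 2, rRNA, tRNA and snoRNA tails changed from 13.2±0.283, 17.3±0.524 and 16.3±0.416 to 13.7±0.356, 18.6±1.18 and 18.4±0.750 nt. Their mean rose by 1.262 nt beside 1.019 nt for the median gene, so a uniform shift cannot be told apart from a change in mRNA tails at that step, where the SDs add up to 1.678 nt. Shorter tails on genes that rose do not account for the shortening to Day 3 in full, since the median change was −2.273 nt for the 2512 genes with no called change in expression against −1.743 nt for called genes. The tailed share of reads fell over the same time, from 42.8% and 41.1% in Log phase and 41.9% and 40.1% on Day 2 to 39.7% and 39.8% on Day 3 and 38.9% and 38.3% on Day 4. Whether both follow from how tails were read was not tested. A change in the tails of most mRNAs with colony age may also hold but was not tested apart from these.

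Reads of rRNA and snoRNA genes lie outside the comparisons and stood above their level in Log phase on Day 3 and Day 4, which is why they are listed here. The rRNA share of tailed reads was 0.245±0.0170% in Log phase, 0.316±0.0690% on Day 2, 0.789±0.0347% on Day 3 and 1.556% on Day 4 (SD 0.00364, n = 2), and the snoRNA share was 0.238±0.0291%, 0.153±0.0261%, 0.397±0.0160% and 0.719%; the differences were not tested. A lower mRNA yield would likely raise all non-coding classes alike, but the tRNA share changed 0.922-fold from Log phase to Day 4 while the rRNA share changed 6.361-fold (0.814 to 1.05 and 6.05 to 6.70 over pairs of libraries). Within colonies the tRNA share rose too, from 0.119±0.0295% on Day 2 to 0.172±0.00905% on Day 3 and 0.219±0.00879% on Day 4. A lower yield on Day 3 and Day 4 than on Day 2 is therefore not excluded as a contribution. A single abundant snoRNA does not carry the snoRNA share, which rose 2.721-fold without SNR40 and 3.023-fold with it. A few do carry much of it: SNR40, SNR24 and SNR4, picked after their values were seen, made 49.8% of the rise, which was 2.09-fold without them, but 50 of the 73 snoRNAs were higher on Day 4 than in Log phase in every pair of libraries and 14 lower. Oligoadenylation of RNAs bound for decay and internal priming on A-rich stretches could both add such reads, and neither was tested.

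On Day 4 against Log phase, 10 genes were called in opposite directions by all reads and by tailed reads, beside 3723 called in the same direction. They are ASC1 (0.44 with all reads, −3.15 with tailed reads, assignment uncertain) and, in the same order, SCS22 (0.49, −0.57), HCM1 (0.83, −0.82, uncertain), CAN1 (1.52, −1.14, uncertain), DSE1 (2.19, −0.53, uncertain), TOM20 (−0.49, 0.43), YSP1 (0.52, −0.67), OXP1 (0.75, −0.89, uncertain), MCM1 (0.99, −0.70, uncertain), RPB10 (0.48, −1.48, uncertain). A snoRNA inside the gene could add reads to it, but 10% of the 10 (1 gene, ASC1, which holds SNR24) have one. Reads assigned to different overlapping genes in the 2 tables could account for part: 7 of the 10 were assigned differently against 295 of the 3723 (7.92%; Fisher exact p = 2.06e-06, two-sided). The uncertain mark and the opposite calls both rest on differences between the deposited read counts, so this test is not independent of how the genes were picked. ASC1, with 2.24 times as many counts as reads, is among the 7 and counts towards both explanations. No biological explanation was tested for these genes.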

How the results depend on the processing

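Every test here was planned before the data were examined except that of only those genes assigned alike by both tables, which was chosen after seeing the data. Counts of genes changed in expression, in the order Day 2, Day 3 and Day 4 against Log phase, Day 3 against Day 2 and Day 4 against Day 3, were 3348, 4085, 4401, 2930 and 1570. They stayed within 1.5 times of this with DESeq2's test (3263, 4003, 4312, 2816 and 1550), with the replicate number as a block (3288, 4049, 4363, 2834 and 1464), and with only those genes assigned alike by both tables (3091, 3758, 4014, 2685 and 1411). They also did so with DESeq2's size factors, with total counts, without the filter, with tailed reads and with only the 4 libraries compared. With total counts, the share higher against Log phase went to 72.8%, 65.3% and 64.5%, as that scaling moves all genes up. Against a 2-fold change the test called 870, 1890, 2368, 432 and 12, fewer because its null hypothesis is wider. Without 1 library at a time, where the lone library is assumed to vary like the other groups, counts ran from 2683 to 3378 for Day 2 against Log phase and 3612 to 4262 for Day 3 against Log phase. They ran from 3965 to 4567 for Day 4 against Log phase, from 2240 to 2902 for Day 3 against Day 2 and from 608 to 2046 for Day 4 against Day 3 (998 without Day 3 replicate 1, 883 without Day 3 replicate 2, 786 without Day 4 replicate 1, 608 without Day 4 replicate 2). Without Day 2 replicate 1 or 2 they rose, to 4258 and 4262, 4553 and 4567, and 2038 and 2046 for Day 3 and Day 4 against Log phase and Day 4 against Day 3, and the cause was not tested.

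Counts of genes changed in tail length, in the same order, were 588, 493, 884, 1606 and 0, and with the replicate number as a block 515, 439, 855, 1521 and 0. With each library's median subtracted they became 280 (141 longer, 139 shorter), 413 (296 longer, 117 shorter), 719 (480 longer, 239 shorter), 487 (338 longer, 149 shorter) and 3 (3 longer, 0 shorter), since this removes what all genes share. Between Day 4 and Day 3, weights without a cap gave 3 and only the 4 libraries compared 11; the cause was not tested. Without 1 library at a time counts ran from 160 to 603 for Day 2 against Log phase (160 without Log phase replicate 2, 238 without Day 2 replicate 1) and 170 to 548 for Day 3 against Log phase (170 without Log phase replicate 1, 224 without Day 3 replicate 1, 209 without Day 3 replicate 2). They ran from 390 to 957 for Day 4 against Log phase (390 without Log phase replicate 1, 587 without Day 4 replicate 1, 458 without Day 4 replicate 2), from 829 to 1575 for Day 3 against Day 2 (829 without Day 3 replicate 1, 997 without Day 3 replicate 2) and from 0 to 1 for Day 4 against Day 3 (1 without Day 3 replicate 1); the cause was not tested. The median tail, 20.42 nt on Day 2 and 18.25 nt on Day 3, moved by more than the spread between libraries to 20.01 nt as a mean weighted by tailed reads on Day 2, and on Day 3 to 18.30 nt by that mean and 18.27 nt with at least 50 tailed reads. The order of the groups held, and the cause was not tested. Correlations of expression and tail changes, run under few alternatives, kept their side of the threshold.

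Of 170 list tests for each readout, 95 for expression and 12 for tails had adjusted p under 0.05 with the preset correlation, against 0 and 0 with the correlation estimated per list. Tail p-values from camera rose also where the estimate lay under the preset 0.01. For iron genes on Day 2 (estimate −0.0214) p went from 0.0124 to 0.0496, and for RNA polymerase I and III subunits (−0.0116) from 0.0185 to 0.0627. The size of the correlation therefore does not account for the loss in full, and the cause was not tested further. Over 464 pairs of a named gene and a comparison, 6815 of 7259 values under an alternative kept direction and side of the threshold, 439 kept direction without passing it and 5 changed sign. These were DED1/HIS3 for Day 4 against Log phase (0.0517 with scaling to total counts, assignment uncertain), CTF4 for Day 4 against Log phase (−0.0262 with tailed reads), TFS1 for Day 3 against Day 2 (0.0455 without Day 2 replicate 1), TPS3 for Day 4 against Log phase (0.0491 with scaling to total counts) and TIF4631 for Day 4 against Day 3 (−0.0154 with tailed reads, assignment uncertain). For TFS1 that range was −0.992 to 0.0455 without 1 library at a time, and the cause was not tested for any of these. Poly(A) site use, its overlap with expression and their alternatives were not run.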

Other observations

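The list tests of this part were chosen before their results were seen. Cytosolic chaperone genes had 10 of 24 higher and 9 lower (10 and 9 adjusted over the list alone, median 0.06) on Day 4 against Log phase, where SSA3 (4.98±0.25) rose and the constitutive SSA2 (−4.06±0.17) and SSB1 (−3.30±0.16) fell. Cell wall genes had 16 of 37 higher and 16 lower (16 and 17 adjusted over the list alone, median −0.05, mean 0.09, 0.40 with scaling to total counts, 0.17 with tailed reads), led by GSC2 (3.55±0.15) and YGP1 (3.28±0.15), where GSC2 encodes a glucan synthase subunit. Proteasome genes had 2 of 37 higher and 21 lower (2 and 21 adjusted over the list alone, median −0.57, higher: RPN14 0.59±0.22) on Day 3, with PRE1 (−1.23±0.15) and RPN2 (−1.25±0.15) lower and their activator gene RPN4 (1.88±0.16) higher. Sulfate and methionine genes had 5 of 26 higher and 12 lower (5 and 12 adjusted over the list alone, median −0.41) on Day 2, led by SAH1 (−1.92±0.19) and CYS4 (−1.53±0.15). From Day 3 to Day 4 they had 4 of 26 higher and 4 lower (4 and 4 adjusted over the list alone, median 0.00017), with the permease gene MUP3 (0.91±0.17) higher. Phosphate genes had 5 of 23 higher and 12 lower (5 and 12 adjusted over the list alone, median −1.43) on Day 4, where the phosphate transporter gene PHO89 (4.10±0.18) rose and the vacuolar polyphosphate gene VTC4 (−2.97±0.18) fell. Iron genes had 6 of 28 higher and 11 lower (6 and 11 adjusted over the list alone, median 0.03, mean −0.12, −0.10 with tailed reads) on Day 2, when FET3 (−1.97±0.15) and FTR1 (−1.30±0.15) fell. From Day 3 to Day 4 they had 10 of 28 higher and 2 lower (12 and 2 adjusted over the list alone, median 0.33, lower: FET4 −0.45±0.16, ATX1 −0.65±0.14), when the cell wall mannoprotein genes FIT3 (1.27±0.20) and FIT1 (1.32±0.29) rose.

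Meiosis and sporulation genes had 36 of 48 higher and 1 lower (36 and 1 adjusted over the list alone, median 1.55, lower: GAS2 −1.69±0.56) on Day 4 against Log phase, with SPO1 (3.09±0.24), SPO74 (4.15±0.36) and REC8 (4.28±0.47), and the meiotic regulator gene IME1 (1.47±0.19) rose from Day 3 to Day 4. Seripauperin genes, whose close paralogs share reads, had 9 of 16 higher (9 adjusted over the list alone, median 1.88), led by PAU23 (2.85±0.26). The a-cell genes had 2 of 17 higher and 2 lower (2 and 2 adjusted over the list alone, median 0.06, −0.20 with tailed reads) from Day 3 to Day 4, where AGA1 (2.06±0.20) and FUS3 (0.53±0.18) rose and FAR1 (−0.53±0.17) fell. Puf3-bound mitochondrial translation mRNAs had 1 of 20 higher and 10 lower (1 and 10 adjusted over the list alone, median −0.43, higher: MDM38 0.56±0.16) from Day 3 to Day 4, led by TUF1 (−0.82±0.14) and COX17 (−0.89±0.16), while PUF3 itself rose.

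A hypothesis that abundant transcripts carry shorter tails was tested across genes within each library, with a test written before its result was seen. Spearman's rho of CPM and tail length was negative in all 8 libraries, from −0.134 at the highest to −0.173, over genes that are not independent replicates. A weak relation of this kind could contribute to the negative correlation of changes, and cause was not tested.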
